A study of Streptomyces hygroscopicus subsp. jinggangensis 5008 and Streptomyces hygroscopicus subsp. jinggangensis TL01 with 16 samples.

How the data were processed

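The series holds 16 arrays of the strains 5008 and TL01 of Streptomyces hygroscopicus subsp. jinggangensis in the media YMG and IND, with 4 arrays per group. Per the labels, total RNA from mycelia was treated with DNase, amplified and labelled with Cy3 by a one-colour kit. Per the file headers, intensity values came from Agilent Feature Extraction, whose processed signal is background-subtracted and detrended within the array and not normalized between arrays. Its version differed between the 2 slides. Per the file headers, other columns hold flags of 0 or 1 for spots well above background, saturated or uneven. The authors deposited a further table of log2 values, whose normalization is not given in the sources used here. Its columns had medians of 8.14 to 8.15 and correlated with the scanner values of the same arrays with r of 0.990 to 0.999. Its scale relative to the scanner values was 0.795 to 0.854 in YMG and 1.21 to 1.29 in IND, so the authors' log2 values compress the YMG and stretch the IND arrays. Of its 9103 entries, 9043 matched a probe of the scanner files.

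Control spots were left out and spots marked as outliers were set to missing. Of 9119 probes, 304 had 21 spots, which were averaged, and 74 shared their sequence with another probe. The log2 processed signal minus the 75th percentile of the array was used as the level. The planned filter asked for probes well above background on all arrays of at least 1 group, and it removed 0 probes. Per the series text, 3 independent experiments were done per condition, while 4 arrays are listed. In each group 1 pair of arrays shared a culture number. These pairs correlated with r of 0.992, 0.993, 0.999 and 0.999, the other pairs of a group with 0.933 to 0.987, and each was averaged to 1 replicate.

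The 12 averaged samples entered 1 fit with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with group means and no block, and the Benjamini-Hochberg threshold was 0.05. Each probe had 1 estimate of the spread, shared by all groups. An SE or p-value therefore mixes the spread of YMG and IND arrays and is not that of the compared groups alone. The prior had 3.29 degrees of freedom and the residual 8. The 6 comparisons were the strain in each medium, the medium in each strain, the mean strain difference and the interaction. The fit was tested on simulated data for 9119 probes with 50 probes changed at each fold. Of those changed 2-fold it recovered 56% for the strain in YMG, 72% for the strain in IND, 84% and 86% for the medium in 5008 and TL01, 84% for the mean and 32% for the interaction. The strain in each medium and the medium in each strain had the same median SE, 0.173, so their shares differ mainly by the probes drawn. The simulated noise was independent between probes and 200 probes were changed, far fewer than passed in the data. These shares are therefore not the sensitivity of the real comparisons.

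The rule for named probes, set before the data were examined, took the 2 largest rises and 2 largest falls per comparison among probes past the threshold whose groups did not overlap. A probe not well above background on any array of a group has only a bound. There the mean of the bright group was set against a floor, the higher of the probe's own signal and the lowest signal well above background on each array. The 27 gene lists fixed before the data were examined matched 0 entries of the files, so no list was tested.

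Chosen after the data were seen were the runs of at least 5 neighbours changed at least 2-fold, and the division of the strain difference in IND into stretches of at least 30 probes at steps with a z of 15 or more. So were the scaling on the median of the longest stretch and the removal of a regional shift. For the latter, a running median over 201 probes of each replicate's deviation from the mean of all samples was subtracted. The planned search for lost runs used the detection flags in both media. After it gave 0 runs, the flags of each medium alone and changes of at least 8-fold or 4-fold were tried, and the 8-fold rule in IND was carried further. The alternatives tried were normexp with an offset of 50, quantile and median scaling, the authors' log2 values, only the 7952 probes well above background on all 16 arrays, outlier spots kept, all 16 arrays as separate samples, blocks, a variance trend, fits of only the groups compared, and leaving out each replicate. Figures were drawn with matplotlib 3.10.9.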

Results

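Streptomyces hygroscopicus subsp. jinggangensis is a filamentous soil bacterium that makes validamycin, an antibiotic used against sheath blight of rice. Transcript levels of the strains 5008 and TL01 were measured on 16 one-colour Agilent arrays after 48 h of fermentation at 37 °C. Each strain was grown in a laboratory medium of yeast extract, malt extract and glucose (YMG) and in an industrial medium based on rice and peanut cake (IND), with 4 arrays in each of the 4 groups. Arrays of a group that shared a culture number were averaged, which left n = 3 per group. Averaged replicates are named by their culture number and not by the replicate number in the labels. The arrays carried 9119 probes of 60 bases. The files do not pair probes with genes, so probes and stretches of neighbouring probes are given by their number in the array design. The files do not state whether these numbers follow the order of genes on the chromosome. Levels are log2 intensities relative to the 75th percentile of the array. The labels do not say whether the replicates came from separate pre-cultures, so p-values measure only the spread between these samples.

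The median probe intensity was 91.7 to 133.4 on the YMG arrays and 486 to 900 on the IND arrays. On the YMG arrays 89.08% to 96.12% of the probes were well above background, and on the IND arrays 99.88% to 100%. All YMG arrays lay on one slide and all IND arrays on another, read with different scanner software versions. Medium, slide and scan therefore cannot be told apart, whereas the strains were compared within a slide. The means of the 10 spike-in control probes spanned 10.2 log2 units in YMG and 3.56 in IND. The spike-ins therefore give no support for reading the IND signals as transcript levels, and every value in IND or between the media stands under this doubt. The number of arrays limits the precision. The stretches of probes named in the text were chosen after their values were seen, the single probes by a rule set before the data were examined.

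The first comparison asked how TL01 differed from 5008 in YMG. Probes 2434 to 2444 were higher in TL01, with a median level of 3.53 ± 0.29 against 0.32 ± 0.27 in 5008 (mean ± SD, n = 3), and all 11 passed the test. Probes 7927 to 7935 stood at 4.20 ± 0.44 in TL01 and -0.54 ± 0.39 in 5008, and all 9 passed. Probes 8777 to 8792 stood at 2.99 ± 0.08 in TL01 and 1.21 ± 0.17 in 5008, and all 16 passed. Probes 183 to 188 were lower in TL01, at -6.51 ± 0.50 against -3.68 ± 0.28, as were probes 8929 to 8935, at -2.73 ± 0.57 against -0.56 ± 0.15. The TL01 level of probes 183 to 188 lay below -5.55, the level there of a probe not well above background, so their difference is no exact size. Probe CUST_4280_PI419532412 rose by 5.73 on the log2 scale (SE 0.33, limma adjusted p = 4.13e-07). Probe CUST_3893_PI419532412, not well above background on the 5008 arrays in YMG, was at least 57.5-fold higher in TL01 (limma adjusted p = 4.74e-06). Probe CUST_1856_PI419532412 fell by 8.39 (SE 0.16, limma adjusted p = 6.80e-11) and was well above background on 2 of the 4 TL01 arrays, so this value is no exact size. Probe CUST_163_PI419532412, not well above background in TL01 in YMG, was at least 187-fold lower there (limma adjusted p = 6.80e-11). Of the 9119 probes, 3564 passed an adjusted p of 0.05 in limma, 1598 higher and 1966 lower in TL01, and 742 and 655 of these changed at least 2-fold. Runs of at least 5 neighbouring probes, each past the threshold and changed at least 2-fold, held 88 of the higher and 59 of the lower probes, against at most 6 and 6 in 1000 shuffles of the list. With normexp background correction 1527 probes passed, 631 of them changed at least 2-fold, against 1397.

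In IND the difference between the strains followed the order of the probes in steps. The 1314 probes from 248 to 1561 had a median difference of -0.67 and the 7009 probes from 1626 to 8634 a median of 0.43. Probes 8635 to 8861 had a median of 1.28, and probes 8862 to 8990 a median of -2.13. The lowest values lay near the start of the list, where probes 165 to 247 stood at -5.0 ± 0.39 in TL01 and 0.56 ± 0.05 in 5008 (mean ± SD, n = 3) and all 83 passed the test. Probes 8832 to 8849 were higher in TL01, at 1.67 ± 0.26 against -0.92 ± 0.19, and all 18 passed. Probes 254 to 265 stood at 5.21 ± 0.98 in TL01 and 3.70 ± 0.46 in 5008, and all 12 passed, or 8 of the 12 without 5008 culture 3 in IND.

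**Figure D1:**
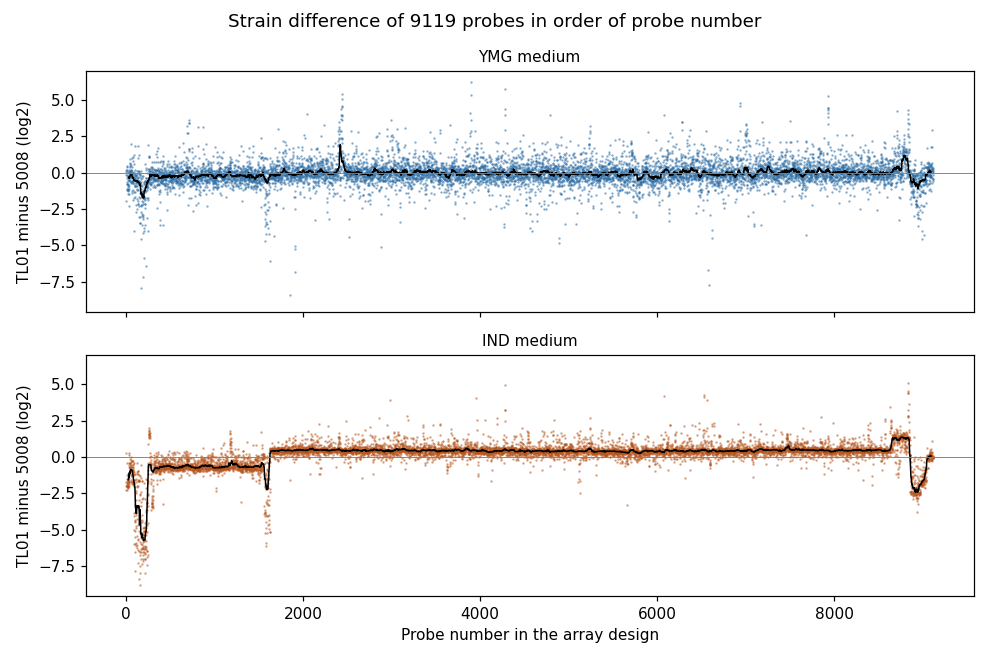
Strain difference (TL01 minus 5008, log2) of the 9119 probes against probe number, in YMG above and IND below, with the running median over 51 probes as a black line. In IND the line steps from -0.67 over probes 248 to 1561 to 0.43 over probes 1626 to 8634; these values are relative to the 75th percentile, and scaling on the median of probes 1626 to 8634 sets that stretch near 0 by construction.

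Probe CUST_8837_PI419532412 rose by 5.08 in IND (SE 0.82, limma adjusted p = 0.000644) and probe CUST_4280_PI419532412 by 4.92 (SE 0.33, limma adjusted p = 6.07e-07). The first had an SD of 2.03 between the 5008 replicates, and its rise was 6.13 without 5008 culture 3 in IND and 4.11 without culture 4. Probes CUST_153_PI419532412 and CUST_147_PI419532412 were not well above background on the TL01 arrays in IND. They were at least 204-fold and at least 183-fold lower there, with limma adjusted p of 8.64e-09 and 4.69e-08. In limma 4926 probes passed, 3526 higher and 1400 lower in TL01, and 539 and 515 of these changed at least 2-fold. Runs of neighbours held 384 of the 515 lower and 135 of the 539 higher probes, against at most 5 and 5 in 1000 shuffles. With the regional shift removed, runs held 56 of 220 lower and 100 of 336 higher probes. Higher and lower are then relative to the neighbouring probes. Probes 78 to 87 and 137 to 144 counted as higher, yet their medians before the removal were -0.98 and -1.42. Before it 0 of them passed as higher, as did 13 of the 31 probes from 252 to 282 and all 18 from 8832 to 8849. The split of the calls depended on the scaling. Higher probes made up 71.6% of the calls, 56.5% after quantile normalization, 31.3% of 2284 calls with median scaling and 19.2% of 2249 calls with scaling on the median of probes 1626 to 8634. Without 5008 culture 5 in IND 3251 probes passed, and with the regional shift removed 1096. The count of at least 2-fold changes, 1054, was 1797 after quantile normalization, 1724 with the authors' values and 556 with the regional shift removed.

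**Figure D2:**
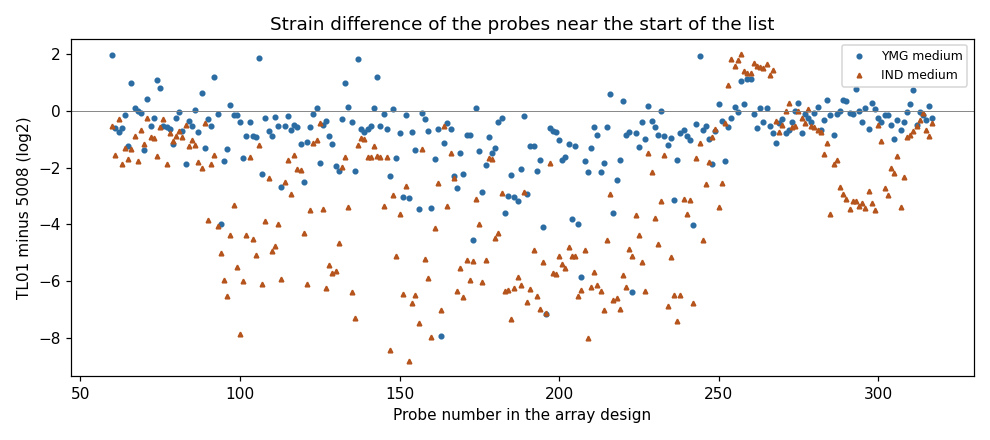
Strain difference (TL01 minus 5008, log2) of single probes near the start of the list against probe number, with circles for YMG and triangles for IND. In IND probes 165 to 247 had a median difference of -5.31, and in YMG -1.23.

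The next comparison asked what the change from YMG to IND did in strain 5008. Probes 252 to 267 rose from -2.13 ± 0.11 in YMG to 3.31 ± 0.44 in IND (mean ± SD, n = 3), and all 16 passed the test. Probes 298 to 309 rose from -3.07 ± 0.15 to 4.34 ± 1.23, and all 12 passed; their median change was 7.50, and 8.12 without 5008 culture 3 in IND. Probes 1472 to 1495 fell from 5.26 ± 0.27 to 1.70 ± 0.49, and all 24 passed. Probes 8802 to 8815 fell from 2.67 ± 0.11 to -0.68 ± 0.09, and all 14 passed. Probe CUST_305_PI419532412, not well above background in YMG, was at least 683-fold higher in IND (limma adjusted p = 1.44e-07), and probe CUST_285_PI419532412 rose by 9.15 (SE 0.89, limma adjusted p = 1.26e-06). Probes CUST_6581_PI419532412 and CUST_8536_PI419532412 fell by 7.02 (SE 0.25, limma adjusted p = 5.81e-10) and fell by 6.97 (SE 0.89, limma adjusted p = 1.36e-05). The last had an SD of 2.53 between the 5008 replicates in IND, and it fell by 8.43, 6.21 and 6.27 without cultures 3, 4 and 5. Without cultures 3 and 4 the rise of probe CUST_285_PI419532412 was 10.13 and 8.42, and the bound for probe CUST_305_PI419532412 was 1019-fold and 469-fold. In limma 7628 of the 9119 probes passed, 4605 higher and 3023 lower in IND, and 3622 and 2021 of these changed at least 2-fold. Higher probes made up 60.4% of the calls, 48.4% with median scaling, 45.5% after quantile normalization and 41.9% with normexp. The medium and the slide cannot be told apart in these values.

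In TL01 the same change of medium raised probes 252 to 267 from -2.30 ± 0.25 to 4.91 ± 1.02 (mean ± SD, n = 3), and all 16 passed the test. Probes 282 to 294 rose from -2.97 ± 0.09 to 1.77 ± 1.71, and all 13 passed; their median change was 4.14, and 5.01 and 3.19 without TL01 cultures 1 and 5 in IND. Probes 2428 to 2444 fell from 3.32 ± 0.14 to -1.23 ± 0.17, and all 17 passed. Probes 1472 to 1480 fell from 4.26 ± 0.34 to 0.60 ± 1.52, and all 9 passed. Probe CUST_257_PI419532412 rose by 9.38 (SE 0.48, limma adjusted p = 9.04e-09), and probe CUST_305_PI419532412 was at least 188-fold higher in IND (limma adjusted p = 4.81e-07), a bound of 377-fold and 113-fold without the same cultures. Probes CUST_8536_PI419532412 and CUST_2438_PI419532412 fell by 8.61 (SE 0.89, limma adjusted p = 2.32e-06) and fell by 8.07 (SE 0.21, limma adjusted p = 1.77e-10). The SE of the first came from the spread shared by all groups. Its SD was 0.38 in YMG and 0.14 in IND in TL01, and 2.53 in 5008 in IND. In limma 7492 probes passed, 5008 higher and 2484 lower in IND, and 3874 and 1495 of these changed at least 2-fold. Higher probes made up 66.8% of the calls, 46.3% with median scaling, 46.4% after quantile normalization and 53.3% with normexp. With normexp 3547 probes passed and changed at least 2-fold, against 5369. At least 2-fold changes went the same way in both strains for 3123 higher and 1239 lower probes, and opposite ways for 82. Here too the medium and the slide cannot be told apart.

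**Figure D3:**
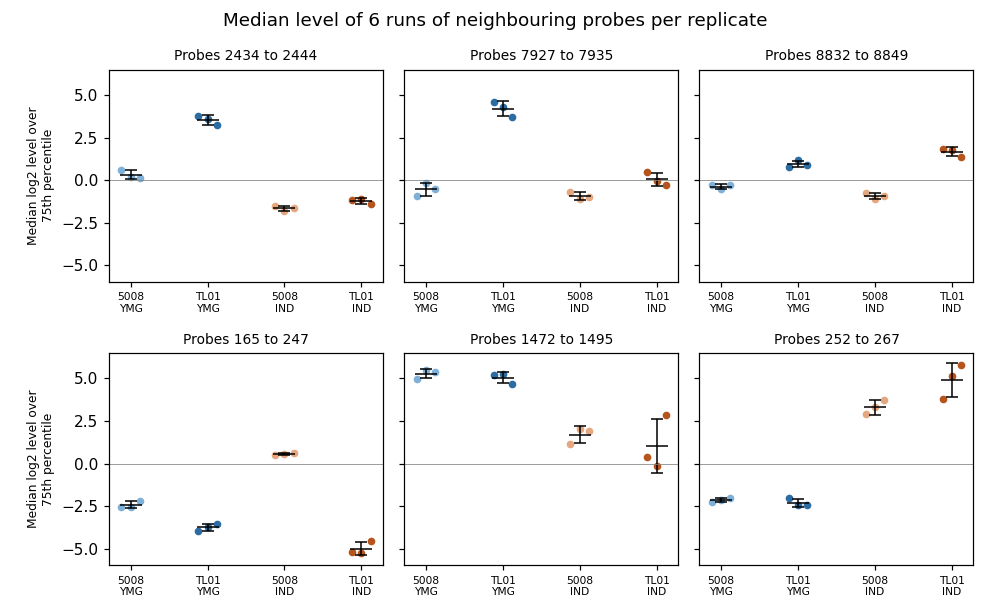
Median log2 level, relative to the 75th percentile of the array, of 6 stretches of neighbouring probes in the 4 groups. Points are the 3 averaged replicates and bars their mean ± SD. Probes 2434 to 2444 stood at 3.53 in TL01 in YMG and between -1.65 and 0.32 in the other groups.

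Averaged over both media, probes 8835 to 8842 were higher in TL01, with a median difference of 3.36, and all 8 passed the test. They stood at 3.71 ± 0.19 against 0.66 ± 0.41 in YMG (mean ± SD, n = 3), and their median difference in IND was 4.01. In IND they stood at 3.51 ± 0.06 in TL01 and -0.18 ± 1.08 in 5008, whose replicates differed widely. Probes 165 to 227 were lower, with a median difference of -3.54, and all 63 passed. This average describes neither medium, as the median was -1.48 in YMG, where 55 passed, and -5.56 in IND. The interaction test was passed by 56 of them. Probes CUST_4280_PI419532412 and CUST_8839_PI419532412 rose by 5.32 (SE 0.24, limma adjusted p = 1.30e-08) and by 4.41 (SE 0.39, limma adjusted p = 4.91e-06). Probe CUST_8839_PI419532412 had an SD of 1.33 between the 5008 replicates in IND. Probes CUST_163_PI419532412 and CUST_196_PI419532412 fell by 7.47 (SE 0.11, limma adjusted p = 5.41e-12) and fell by 7.16 (SE 0.21, limma adjusted p = 8.27e-10). The first was not well above background in TL01 in YMG and the second was on 2 of the 4 arrays there, so these values are no exact sizes. In limma 4176 probes passed, 2541 higher and 1635 lower in TL01, and 521 and 469 of these changed at least 2-fold. Higher probes made up 60.8% of the calls, 54.2% after quantile normalization, 44.4% with median scaling and 32.0% with scaling on the median of probes 1626 to 8634.

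The interaction tested whether the strain difference itself differed between the media. Probes 2434 to 2444 had a median strain difference of 3.92 in YMG and 0.44 in IND, and all 11 passed the interaction test. Probes 1909 to 1914 had a median strain difference of -3.78 in YMG and 1.05 in IND, and all 6 passed. Their TL01 levels in YMG were uneven, at -2.16, 0.54 and -1.96 in cultures 1, 4 and 5, against 2.23 ± 0.21 in 5008 (mean ± SD, n = 3). The stretch holds probe CUST_1912_PI419532412, given below. Probes 90 to 118 had medians of -0.53 in YMG and -4.05 in IND, and all 29 passed. The interaction term of probe CUST_6581_PI419532412 was 8.69 (SE 0.35, limma adjusted p = 6.32e-08). That of probe CUST_1912_PI419532412 was 8.29 (SE 1.67, limma adjusted p = 0.00301), with an SD of 3.11 between the TL01 replicates in YMG. Without TL01 cultures 1, 4 and 5 in YMG it was 7.28, 10.08 and 7.50, and without TL01 cultures 1 and 5 in IND 8.91 and 7.65. Probe CUST_220_PI419532412 had a term of -6.14 (SE 0.58, limma adjusted p = 2.11e-05). Probe CUST_100_PI419532412, with a limma adjusted p of 3.02e-08 and a negative term, was well above background in 5008 in IND and on no array of the other groups. In limma 3651 probes passed, 2525 with a higher and 1126 with a lower strain difference in IND. Higher terms made up 69.2% of the calls, 52.6% after quantile normalization, 44.1% with median scaling and 30.8% with scaling on the median of probes 1626 to 8634. With normexp 2250 probes passed, and with the regional shift removed 2305.

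The strain differences in the 2 media were then set against each other. Across the 9119 probes, which are not independent replicates, they correlated with r = 0.381 (Spearman rho 0.305). Of the 2206 probes past the threshold in both media, 1499 had the same direction. At least 2-fold higher in TL01 in both media were 191 probes, against 43.9 for independent lists, and at least 2-fold lower 185, against 37.0. Probes 8832 to 8849 had median strain differences of 1.60 in YMG, where 12 of the 18 passed, and 2.55 in IND, where all 18 passed. The correlation was 0.326 without the probes of the 7 runs that were at least 8-fold lower in IND, and 0.254 with normexp.

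The design also asked for neighbouring probes well above background on every 5008 array and on no TL01 array in both media. No probe met this, so there were 0 such runs. In IND alone 5 probes and in YMG alone 28 met it, also with 0 runs. In YMG 48 probes met it with the strains exchanged. An added rule, at least 8-fold lower in TL01 in IND with an adjusted p under 0.05, took 159 probes. Of these, 127 lay in 7 runs of at least 5 neighbours, the longest from probe 145 to probe 245. At least 80% of the probes of a run had to meet the rule, so the runs also held neighbours that did not and spanned 155 probes. The median intensity of these 155 probes was 1945 to 2764 on the 5008 arrays in IND and 47.3 to 49.7 on the TL01 arrays. In YMG it was 44.5 to 58.2 in 5008 and 26.5 to 32.5 in TL01. On the TL01 arrays in IND 92.9% to 96.1% of them were still well above background. On the YMG arrays 83.23% to 92.26% of them were in 5008 and 63.87% to 70.97% in TL01.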

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

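The tests of non-specific hybridisation and of a raised background, the step in YMG, the test of GC content as the whole cause, the agreement within YMG and the tests of the runs were chosen after the result was seen; the rank correlation between media, the brightest probes, the bound of 0.75 for GC content and the splits were not. The demand that a whole bootstrap interval lie past a bound was also added after the values were seen. Without it, -0.74 would have excluded the explanation it tests, and so would -3.28 and 4.36, which set different probes against each other and decide nothing. The bootstrap drew probes and not replicates. Neighbouring probes were not independent, with r = 0.814 between the strain differences of adjacent probes in IND. The intervals are therefore too narrow and do not measure the spread between replicates. The test of scattered variants replaced one that asked for 80% of the probes in runs, where 79.9% were found, and the test of a low transcript level replaced one on detection flags, which nearly all probes pass in IND.

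The count of probes whose strain difference differed between the media, 3651 in limma, drew attention because the difference itself passed its test. Of 100 drawn splits of the strains within each medium, 2 gave as many, the real one and the one with the strains exchanged in 1 medium, which turns the interaction into the mean difference and gave 4176. The highest of the others was 1298. The splits set the count against no strain difference in either medium. A strain difference in 1 medium alone would also make the real split stand out, so they do not test the interaction itself. For the mean strain difference 1 of 100 splits gave as many as 4176, the highest other being 3651 from the same exchange. For the other comparisons the splits are too few for a share under 0.05, with 1 of 10 splits giving as many in each. The counts were 3564, 4926, 7628 and 7492, and the highest other splits gave 0, 9, 0 and 0 probes.

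A signal outside the comparisons came from the spike-in control probes. The brightest in YMG had a log2 signal of at least 12 on each YMG array and of 3.20 to 4.20 on the IND arrays. The means of the 10 spike-in probes spanned 10.2 log2 units in YMG and 3.56 in IND. Of these probes, 6 were brighter on every YMG array than on any IND array, and 4 were dimmer. The spike-in probe dimmest in YMG rose from a mean of 2.03 there to 5.07 in IND. The comparisons do not use these probes, but they bear on each one that draws on IND arrays. Without the gradient, values in IND and between the media are in doubt as transcript levels. The cause of the spike-in difference was not tested, so it does not show by itself that the other probes are affected.

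Probes that were dim in YMG gave high signal in IND. A raised background on the IND slide is argued against as far as the negative controls show it. Before background subtraction (spot medians in YMG, spot means in IND) they rose by 28.3 and the dimmest probes of 5008 by a median of 460. The ratio was 0.0615 (95% interval 0.0597 to 0.0635). The negative controls do not show the rise of the 4 spike-in probes that were dimmer in YMG, whose cause was not tested. For the run probes, non-specific hybridisation was tested in runs found without 1 replicate of each strain. The dim probes of these runs differed between the strains in the left-out replicates by medians of -6.28 to -5.16 (-5.41 to -4.49 for the last). Their strain difference on the same slide thus recurred. The runs were taken for that difference and the replicates were closely alike, so the outcome was largely set in advance. It leaves non-specific hybridisation open. For other probes it stays open too, as its test, -3.28 (-3.75 to -2.91) between run probes and the dimmest others in TL01, compares different probes. Within the dimmest probes of 5008 the levels in both media correlated with a rho of 0.142 (0.107 to 0.178), consistent with genomic DNA in the labelled material, while 1 YMG replicate and the mean of the others gave 0.867 to 0.926 and the YMG levels of both strains 0.777. Over all probes rho between the media was 0.491 in 5008 and 0.593 in TL01, so the IND levels also followed the YMG levels, the labels state a DNase treatment and a cRNA kit, and a response to the medium, which would lower rho too, was not tested, since medium and slide cannot be told apart.

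The strain difference in IND changed in steps along the list. A difference in transcript level present in both media is argued against, since the step between probes 248 to 1561 and 1626 to 8634 was 1.09 in IND and 0.181 in YMG, a ratio of 0.166 (0.136 to 0.191). This interval is over probes alone. Over replicates in IND, the second stretch minus the first was -1.44 ± 0.17 in 5008 and -0.33 ± 0.09 in TL01 (mean ± SD, n = 3). The spread of the step between replicates in YMG was not tested. GC content as the whole cause is argued against too, since among probes of like GC the step was 1.13, 1.01 and 0.703 (0.644 to 0.761 for the last) of the overall one, from the lowest to the highest GC; a part of the step from GC stays open, as the last misses the bound of 0.75. Genomic DNA that carries the copy number of each region remains a candidate explanation only if probe numbers follow the chromosome, which the files do not state, and the step in the brightest 10% was 0.532 (0.342 to 0.718) of that in the other probes, which decides neither way. A strain difference in transcripts in IND alone was not tested.

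Genes missing from the TL01 cultures were 1 of the explanations weighed for the runs far lower in TL01 in IND. The stretches between probes 104 and 247, which hold the longest run, had a mean GC content of 57.0% to 59.9%, against 66.3% over probes 1626 to 8634. A part of GC content in the runs was not tested. Scattered sequence variants are argued against for the runs, as 127 of the 159 probes, taken by their change alone, lay in runs and 0 did in each of 1000 shuffles, and they stay open for the probes outside runs. A low transcript level stays open, since its test, 1.23% (0.512 to 1.98) of the dimmest other probes at or below the runs' median, compares different probes and the runs were taken for their low level. For missing genes, the first test put the runs 4.36 log2 units (3.92 to 4.66) above the negative controls, a value that by itself spoke against missing genes. It cannot decide, since it compares different probes, and the spike-in probes on the IND arrays lay above the negative controls too. Their means were 3.66 to 7.22 log2 units, against 0.928 to 1.59 for the negative controls over all arrays. This test was replaced after its value was seen by the strain difference in YMG of the 51 run probes brightest there. These differences ran from -7.93 to 1.93, with 31 of the 51 past the threshold and lower in TL01. Their median was -0.74 (-1.15 to -0.57), which leaves missing genes open. On the TL01 arrays in YMG 63.87% to 70.97% of the 155 run probes were well above background, against 83.23% to 92.26% in 5008. These shares speak against missing genes for the probes detected in TL01, unless other sequences gave their signal, which was not tested. For the run probes not detected there, missing genes stay open.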

How the results depend on the processing

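Chosen after the result was seen were the removal of the regional shift, the scaling on the longest stretch, the correlation without run probes, and the run rules other than the planned ones. Of 154 alternative counts 147 lay within 1.5 times the reported one, and all 606 alternative values of the named probes kept direction and threshold side. The named probes were taken for the largest changes past the threshold, so this was largely set in advance and does not speak for other probes. For the strain in YMG, normexp gave 1527 probes. For the strain in IND, median scaling gave 2284, scaling on the longest stretch 2249, the regional shift removed 1096 (733 shared with the reported calls), and leaving out 5008 culture 5 in IND 3251. For the interaction, normexp gave 2250 and the regional shift removed 2305. The correlation of the strain differences was 0.254 with normexp, 0.292 for probes well above background on all arrays, 0.309 with the regional shift removed and 0.326 without run probes. Of the 154 alternative counts of at least 2-fold changes 5 moved by over 1.5 times: 631 for the strain in YMG and 3547 for the medium in TL01 with normexp, and for the strain in IND 1797 with quantile normalization, 1724 with the authors' values and 556 with the regional shift removed. The runs rose from 0 to 7 with the 8-fold and 12 with the 4-fold rule in IND. The cause was not tested.

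Leaving out 1 replicate gave 2952 to 3751 probes for the strain in YMG, 3251 to 5245 for the strain in IND, 7365 to 7716 and 7209 to 7533 for the medium in 5008 and TL01, 3666 to 4302 for the mean and 2872 to 3682 for the interaction. The correlation ranged from 0.364 to 0.387.

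The replicate numbers in the labels did not pair the samples: 3 of 24 same-numbered pairs had deviations correlated over 0.1 (-0.176 to 0.352). With the replicate block on 16 arrays the counts were 4312, 6473, 7928, 7822, 5162 and 4718, in the order strain in YMG, strain in IND, medium in 5008, medium in TL01, mean and interaction. With the culture number as a replicate block they were 3050, 3621, 7471, 7399, 3524 and 3009. Neither ended the direction or threshold side of a named probe.

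Not run were the tests of gene lists, which had no members, the brightest probe per gene, since no probe is paired with a gene, and the fit with no filter, since the filter removed nothing. Signal over background limits the values of probes not well above background, which were more on the YMG arrays.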

Other observations

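The stretches of probes given here were chosen after the result was seen. Probes 1617 to 1624 were lower in TL01 in IND, with a median strain difference of -4.17 and all 8 past the threshold. In YMG their median was -1.29, and 6 of the 8 passed. With the regional shift removed from both media the medians were -3.47 and -0.81. Probes 1173 to 1179 had a median strain difference of 1.22 in IND, where 6 of the 7 passed (4 without 5008 culture 4 in IND), and of 0.38 in YMG, where 0 passed as higher. With the regional shift removed from both media these medians were 1.65 and 0.47. Probes 567 to 578 rose from YMG to IND in both strains, with medians of 3.31 in 5008 and 2.85 in TL01. Probes 5796 to 5813 fell in 5008 with a median of -2.07, and 11 of the 18 passed in TL01, with a median of -0.90, or 6 without TL01 culture 1 in YMG.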
